A study of Homo sapiens with 29 samples.

How the data were processed

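RNA of 2 human diffuse large B-cell lymphoma lines, DHL4 and DHL6, was hybridised to an Affymetrix human gene expression array, a high-throughput plate format of a short-oligonucleotide design with 22277 probe sets. Cells had received R406, an inhibitor of the tyrosine kinase SYK, at 1 µM for 2, 6, 24 or 48 h, or the solvent DMSO. Per the labels' protocols, cells grew in RPMI medium and RNA was extracted with Trizol. The labels define 10 groups on 29 arrays: DMSO and 4 R406 times in each line, with 3 arrays per group except DHL4 DMSO, which has 2 here. The labels give no time for the DMSO arrays, although the series' design text lists times for R406 and solvent alike, so these arrays may come from 1 or several times. Each R406 time was set against the same DMSO arrays of its line, so treatment time could not be separated from culture time. Nothing in the labels says whether arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

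The deposited values were log2 expression summarised per probe set by RMA, per the submitters' processing notes. RMA corrects background, normalizes quantiles across arrays and fits a robust mean over the probes of a set; its version, and which arrays were normalized together, are not given in the sources used here. The deposited log2 values ran from 1.99 to 13.5. RMA pulls dim probe sets together near the lower end, so fold changes of dim genes are understated, and a gene at that floor in DMSO cannot show a fall. The number of arrays limits the precision of every value.

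Probe sets were named from the platform's annotation, and symbols were updated through Entrez identifiers. Of the 22277 probe sets, 19724 had a single symbol (19707 of them matched by Entrez identifier), 568 had several, 1923 had no listed gene and 62 were array controls. Each gene was represented by its probe set of highest mean over all arrays among those with a single symbol, which gave 12165 genes, 4505 of them with more than 1 probe set. No reference genome was used here, and chromosome positions are not given. Results for probe sets with several symbols, XIST and genes of the Y chromosome were left out of the named genes. Some genes of the plan are not reported here.

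A linear model of the 10 group means was fitted to all 29 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 19 residual and 5.05 prior degrees of freedom. Benjamini-Hochberg adjustment over the 12165 genes was applied per contrast, and a gene was called changed at an adjusted p below 0.05. The contrasts were R406 minus DMSO at each time as the mean of both lines (6 R406 arrays against 5 DMSO arrays), the same in each line, the difference of the responses (DHL6 minus DHL4), late (24 and 48 h) minus early (2 and 6 h) R406 arrays in each line, and DHL6 minus DHL4 in DMSO. Every log2 fold change has its standard error (SE) from this model. Correlations of the 2 lines' fold changes were taken across genes, which are not independent replicates.

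The text names genes by a rule set before the data were examined. For each time in the mean of both lines these are the 5 largest rises and 5 largest falls among called genes of the same sign in both lines, and at most 4 called members of each gene list by absolute change. For differences between lines they are the 3 largest called each way, for late against early and for DMSO the 5 largest called each way. SYK, HRK, BCL2L11, BCL6, MYC, EGR1, DUSP6, CCND2, KLF2, TXNIP, HMGCS1, SQLE, INSIG1 and CYP1A1 were always included. A few further members of named groups are given with their values and were chosen after their values were seen.

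The same plan held 36 gene lists with 623 members, of which 551 were measured. They cover cholesterol synthesis and uptake, fatty acid synthesis, sterol efflux, FOXO targets, death-promoting and survival-promoting BCL2 family members, B-cell receptor signalling components, immediate early genes, ERK feedback genes, chemokines and activation markers induced by the receptor, NF-kB targets, NFAT and calcium-induced genes, MYC targets and ribosome synthesis, ribosomal proteins, DNA replication, mitosis, G1 cyclins and CDK inhibitors, p53 targets, ATF4 amino acid stress, endoplasmic reticulum (ER) chaperones, heat shock, glycolysis, oxidative phosphorylation, germinal centre, plasma cell and pan-B-cell genes, MHC class I and class II, interferon response, aryl hydrocarbon receptor targets, NRF2 targets, autophagy and lysosome, histones, and markers of T cells, monocytes and macrophages, and fibroblasts and endothelium. Some genes stand in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 36 lists and the contrasts of a kind together. Counts of list members use the adjustment over all genes, and counts "adjusted over the list alone" repeat it within the list.

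The gene-level fit and the list test were tested on simulated data. Of 200 simulated changes among 12165 genes, the mean of both lines at 24 h recovered 46 of 67 at a log2 size of 0.5 and 67 of 67 at a size of 1, with 8 false calls. DHL4 at 24 h recovered 10 of 67 and 57 of 67, and the difference between lines at 24 h 7 and 42 of 67. In a simulated comparison at 24 h, the list test called the 1 shifted list and none of the others (0 calls). The simulated genes varied independently of each other, so this could not show false calls that come from correlated list members.

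The alternatives fixed before the data were examined were centring each array on its median, quantile normalization, array weights, eBayes with trend and robust settings, only the compared groups in the fit, all probe sets, the mean of a gene's probe sets, leaving out the dimmest genes, a block for the replicate number, camera with an estimated correlation, fry, and leaving out each of the 29 arrays in turn. Another pair of alternatives was chosen after seeing the data: leaving out 4 arrays whose upper quartile of log2 values lay below 5, and the ACTB 3'-minus-5' difference as a covariate. That difference, between the array's control probe sets for the ends of the ACTB transcript, rises with loss of the 5' end of RNA. Quantile normalization and median centring both assume that most genes do not shift together, so the share of rising among changed genes depends on them.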

Results

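Gene expression was measured by array in DHL4 and DHL6, 2 lines established from human diffuse large B-cell lymphoma, a cancer of mature B cells. R406 inhibits SYK, the tyrosine kinase that passes on signals of the B-cell receptor. Cells received 1 µM R406 for 2, 6, 24 or 48 h or the solvent DMSO, with 3 arrays per group and 2 for DHL4 in DMSO, 29 arrays in all. Values are log2 expression as the authors deposited them, given as log2 fold change ± SE unless stated otherwise. Replicate arrays correlated at r between 0.978 and 0.996 across the 12165 genes, and no pair held identical values (0 pairs). Whether the arrays of a group came from separate cultures is not stated, so each p-value measures the spread between these arrays, and their number limits the precision. All 4 times share the DMSO arrays of a line, so similar results at several times are not independent of each other. The labels give these DMSO arrays no time, although the design text lists times for R406 and solvent alike. A change from DMSO can therefore include culture time. Where a gene lies near the RMA floor in 1 of the compared groups, its change is a lower bound, and the order of such genes is not a measured order. A mean of both lines can come from 1 line: of 489 called means of genes chosen for naming, 256 were called in both lines, 115 in DHL4 only, 93 in DHL6 only and 25 in neither, and 46 had opposite signs in the lines.

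The series set out to profile the transcriptional response of the lines to R406, and the earliest time was 2 h. Genes of sterol and fatty acid synthesis, protein folding and ribosome synthesis fell together at 2 h in the mean of both lines. The largest rises were those of BACH2, a transcriptional repressor that restrains plasma cell differentiation (2.89 ± 0.11, a 7.39-fold rise over 5 DMSO arrays in 6 R406 arrays), CXCR4, a chemokine receptor (2.45 ± 0.09), RUBCNL, an autophagy regulator (2.22), KANK2 (2.01) and TUT7, an RNA uridylyltransferase (1.80). The largest falls were those of LMO2, a transcription cofactor of germinal centre B cells (-2.81 ± 0.13), PTPN6, a tyrosine phosphatase that dampens receptor signals (-2.49 ± 0.17), CD72, an inhibitory B-cell co-receptor (-2.24), PHACTR1 (-2.21) and KMO, an enzyme of tryptophan breakdown (-2.18). These 10 genes had the same sign in both lines, and their highest adjusted p was 7.65e-06 (KMO, limma). LMO2 ended near the floor (3.09 in DHL4, 2.90 in DHL6), as did PTPN6 (3.54 and 3.57). HRK, a death-promoting BCL2 family member, rose by 1.47 ± 0.17 in the mean, with 0.48 ± 0.25 in DHL4 (adjusted p = 0.284) and 2.46 ± 0.23 in DHL6 (adjusted p = 5.40e-08). The other probe sets of KANK2 (0.08) and HRK (-0.02 and 0.28) were not called at 2 h.

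Among the gene lists at 2 h, 13 of 18 measured members of cholesterol synthesis and uptake fell and 0 rose (16 fell adjusted over the list alone, list median -0.74, camera adjusted p = 6.36e-18), led by HMGCS1, which makes the precursor of mevalonate (-1.58 ± 0.11), and SQLE, the squalene epoxidase (-1.17 ± 0.08). Of 12 fatty acid synthesis genes, 10 fell, also adjusted over the list alone (median -0.54, adjusted p = 1.30e-07), with FADS1 at -1.34 and FASN at -1.19. The other FASN probe set, at 0.05, was not called. Of 27 MYC targets and ribosome synthesis genes, 19 fell (21 adjusted over the list alone, median -0.45, adjusted p = 2.57e-14), among them NOP16 (-1.18) and DKC1 (-0.86). Of 17 ER chaperone genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.38, adjusted p = 5.55e-09), with SDF2L1 at -1.31 and HSPA5 at -1.03. Of 13 heat shock genes, 9 fell, also adjusted over the list alone (adjusted p = 1.20e-08), with HSPH1 at -1.01. Of 29 mitosis genes, 7 rose (11 adjusted over the list alone, median 0.26, adjusted p = 3.90e-07), led by CDC25C, a phosphatase that activates CDK1 (1.13), with adjusted p = 0.263 with an estimated correlation. The other CDC25C probe sets, at 0.02 and 0.28, were not called. Of 18 NF-kB targets, 4 rose and 2 fell, also adjusted over the list alone (median 0.13, adjusted p = 0.0261). The risers were led by PIM2, a survival kinase (1.36), and NFKBIA, an inhibitor of NF-kB (1.07). Across all genes limma called 1591, of which 502 rose and 1089 fell, 47 and 130 of them by at least 2-fold. After quantile normalization 811 rose and 859 fell. Without replicate 1 of DHL4 in DMSO the count was 1047, and the call of the NF-kB list was lost without replicate 1 of DHL4 at 2 h (median 0.14), with only the compared groups in the fit (0.13) and over all probe sets (0.04).

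After 6 h, the falls of the lipid and ribosome synthesis lists were accompanied by lower MHC class II transcripts and higher FOXO targets in the mean of both lines. KANK2, a cytoskeletal adaptor (2.73), RUBCNL (2.71), CXCR4 (2.48), BACH2 (2.28) and CHST15, a sulfotransferase (2.19), rose most, KANK2 by 6.63-fold. KMO (-3.18), PHACTR1 (-2.78), LIMA1, an actin-binding protein (-2.69), PTPN6 (-2.55) and LMO2 (-2.53) fell most, and the highest adjusted p of these 10 genes was 1.41e-08 (KMO, limma). The other KANK2 probe set stood at 0.28 and was not called. SYK itself rose by 1.09 ± 0.13 (adjusted p = 7.11e-07, 6 R406 against 5 DMSO arrays), and HRK by 2.12 ± 0.17. MME, the surface marker CD10 of germinal centre B cells, rose by 2.07.

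By list at 6 h, 15 of 18 cholesterol genes fell (17 adjusted over the list alone, median -1.08, adjusted p = 4.84e-24), with HMGCS1 at -1.84 and DHCR7 at -1.55, and 9 of 12 fatty acid genes fell, also adjusted over the list alone (median -0.63, adjusted p = 9.37e-09), with FASN at -1.45 and SCD, the stearoyl-CoA desaturase, at -1.35. Of 17 ER chaperone genes, 11 fell and 2 rose, also adjusted over the list alone (median -0.53, adjusted p = 1.20e-10), HSPA5 at -1.76 and MANF at -1.44. MYC targets fell for 18 of 27 (20 adjusted over the list alone, median -0.40, adjusted p = 5.48e-13) and heat shock genes for 7 of 13, also adjusted over the list alone (adjusted p = 0.000119). Of 13 MHC class II genes, whose products present antigen to T cells, 8 fell, also adjusted over the list alone (median -0.36, adjusted p = 2.44e-07), HLA-DQA1 at -1.33 and HLA-DQB1 at -1.18. The other HLA-DQA1 probe set, at -0.32, was not called. Of 18 immediate early genes, 7 fell and 0 rose (7 and 1 adjusted over the list alone, median -0.12, adjusted p = 0.00211), with IER2 at -1.57 and EGR1 at -0.90. EGR1 in DHL4 lay near the floor in DMSO, at a log2 level of 3.23. Its other probe set stood at -0.04 in the mean and was not called. Of 23 FOXO targets, 10 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.34, adjusted p = 0.000344), led by GADD45A (2.14) and CDKN1B, a cell cycle inhibitor (1.29). Both were called in DHL4 (3.67 and 2.02) and not in DHL6 (0.60 and 0.57). NF-kB targets rose for 4 of 18 (5 adjusted over the list alone, adjusted p = 0.0158), a call lost over all probe sets, where the list median was 0.01.

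Mitosis genes stood higher at 6 h, 18 of 29 (23 adjusted over the list alone, median 0.52, adjusted p = 2.94e-15), with CDC25C at 1.42 and KIF20A at 0.96, but adjusted p = 0.0774 with an estimated correlation. Of 28 DNA replication genes, 10 fell (13 adjusted over the list alone, median -0.22, adjusted p = 0.000218), CDC6 at -0.91, with adjusted p = 0.350 with an estimated correlation. Of 19 glycolysis genes, 7 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 0.000552, adjusted p = 0.0978 with an estimated correlation). Of 10 MHC class I genes, 4 fell (5 adjusted over the list alone, adjusted p = 0.0180, adjusted p = 0.0802 with an estimated correlation), with HLA-B at -0.48. Limma called 1783 genes in all, 782 higher and 1001 lower, 102 and 147 of them by at least 2-fold. After quantile normalization 1017 were higher and 984 lower.

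The response in the mean of both lines was broadest at 24 h. PRKCB, a protein kinase C isoform downstream of the B-cell receptor, rose by 4.43 ± 0.17 (21.6-fold), APOD, a lipid-binding apolipoprotein, by 4.42, HRK by 3.92 ± 0.17, CHST15 by 3.85 and PHYH, a peroxisomal hydroxylase, by 3.79. KMO fell by 3.86, LIMA1 by 3.20, PLEK, pleckstrin, by 3.13, PHACTR1 by 3.02 and HTR3A, a serotonin-gated channel subunit, by 2.90. The highest adjusted p of these 10 genes was 1.19e-10 (KMO, limma, 6 R406 against 5 DMSO arrays). In DHL4 in DMSO, APOD (2.78), PHYH (3.34) and HRK (3.60) lay at or near the floor, so their rises are lower bounds. PHACTR1 ended there in both lines (2.99 and 2.60), LIMA1 in DHL4 (3.21) and KMO in DHL6 (3.42). The HTR3A fall was measured in DHL4 (-5.76), as DHL6 lay at the floor in DMSO with a log2 level of 3.10. SYK rose by 2.27 ± 0.13, from a log2 level of 7.41 to 9.34 in DHL4 and from 5.16 to 7.77 in DHL6.

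At 24 h, genes of ribosome synthesis, DNA replication, heat shock and lipid synthesis fell. Of 27 MYC targets, 25 fell (26 adjusted over the list alone, median -1.16, adjusted p = 2.03e-23), SRM, the spermidine synthase, at -2.21 (-4.10 in DHL4, -0.32 in DHL6 and not called there) and NME1 at -1.91. Of 28 DNA replication genes, 26 fell (27 adjusted over the list alone, median -1.16, adjusted p = 4.65e-21), MCM4, a helicase subunit, at -1.82. Of 13 heat shock genes, 10 fell, also adjusted over the list alone (median -0.92, adjusted p = 3.41e-09), HSPA8 at -1.84. Of 18 cholesterol genes, 15 fell, also adjusted over the list alone (median -1.23, adjusted p = 3.86e-14), with HMGCS1 at -2.64 and DHCR7 at -2.41. Of 12 fatty acid genes, 10 fell, also adjusted over the list alone (median -0.73, adjusted p = 2.13e-06), with SCD at -2.27 and FASN at -1.97. Mitosis genes fell for 16 of 29 and rose for 2 (16 and 3 adjusted over the list alone, median -0.37, adjusted p = 8.86e-05), among them MKI67 (-1.42) and CCNA2 (-1.33), with adjusted p = 0.373 with an estimated correlation. ER chaperones fell for 10 of 17 and rose for 2 (11 and 3 adjusted over the list alone, adjusted p = 0.000443, adjusted p = 0.0978 with an estimated correlation), with HSPA5 at -1.54 and XBP1, a transcription factor of the unfolded protein response, at 1.27. Glycolysis genes fell for 10 of 19 and rose for 2 (11 and 2 adjusted over the list alone, median -0.37, adjusted p = 0.000115, adjusted p = 0.0669 with an estimated correlation), LDHA at -1.37. Oxidative phosphorylation genes fell for 16 of 24 and rose for 3 (16 and 4 adjusted over the list alone, median -0.35, adjusted p = 0.000119, adjusted p = 0.175 with an estimated correlation), NDUFS1 at -0.91.

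Lists that rose at 24 h included FOXO targets, with 12 of 23 higher and 1 lower (15 and 1 adjusted over the list alone, median 0.43, adjusted p = 2.13e-06), led by GADD45A (3.39) and PIK3IP1, an inhibitor of PI3 kinase (2.37). Of 23 B-cell receptor signalling components, 12 rose and 4 fell (13 and 4 adjusted over the list alone, median 0.32, adjusted p = 0.000257). PRKCB, SYK and PIK3CD (1.64, its other probe set at 0.17 and not called) rose most. The fallers were PTPN6 (-2.50), MALT1 (-0.98), VAV1 (-0.85) and FCGR2B (-0.40). Of 28 interferon response genes, 8 rose and 1 fell, also adjusted over the list alone (median 0.12, adjusted p = 0.0113), with OAS1 at 2.70 and SP110 at 2.14. Of 29 ribosomal protein genes, 14 rose (16 adjusted over the list alone, median 0.13, adjusted p = 0.000875), by small amounts such as 0.36 for RPS9. Of 21 ATF4 targets of amino acid stress, 9 fell and 4 rose (9 and 5 adjusted over the list alone, median -0.05, adjusted p = 0.0474, adjusted p = 0.279 with an estimated correlation), ASNS, the asparagine synthetase, at -1.25. The ATF4 call was also lost under several alternatives, such as quantile normalization (median -0.07) and centring (-0.11), and without replicate 1 of DHL4 in DMSO (-0.06), replicate 3 of DHL6 in DMSO (-0.03), replicate 2 of DHL4 at 24 h (-0.01) or replicate 3 of DHL6 at 24 h (-0.07). Limma called 3757 genes at 24 h, 1646 higher and 2111 lower, 332 and 505 of them by at least 2-fold.

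After 48 h, genes of lipid synthesis, DNA replication and mitosis were lower than in DMSO. CHST15 (3.08, an 8.44-fold rise), PRKCB (2.68), GADD45A, a stress and growth-arrest gene (2.45), TCL1A, an AKT co-activator (2.23), and BACH2 (2.18) rose most. KMO (-2.91), PHACTR1 (-2.70), LMO2 (-2.41), ATF5 (-2.24) and HMGCS1 (-2.23 ± 0.11) fell most, and the highest adjusted p of these 10 genes was 7.63e-08 (KMO, limma). PRKCB rose by 1.08 in DHL4 and 4.29 in DHL6. SYK rose by 1.80 ± 0.13. HRK stood at 1.96 ± 0.17 in the mean, with 0.44 ± 0.25 in DHL4 (adjusted p = 0.424) and 3.49 ± 0.23 in DHL6 (adjusted p = 4.70e-11).

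By list at 48 h, 15 of 18 cholesterol genes fell (17 adjusted over the list alone, median -1.16, adjusted p = 8.08e-22), SQLE at -1.55, and 9 of 12 fatty acid genes fell, also adjusted over the list alone (median -0.53, adjusted p = 2.43e-07), SCD at -1.68. Of 29 mitosis genes, 26 fell (28 adjusted over the list alone, median -0.77, adjusted p = 7.69e-23), PLK1, a mitotic kinase, at -1.50. Of 28 DNA replication genes, 23 fell (24 adjusted over the list alone, median -0.67, adjusted p = 3.85e-17), MCM10 at -1.82. Of 21 ATF4 targets, 12 fell and 1 rose (14 and 1 adjusted over the list alone, median -0.39, adjusted p = 2.15e-08), ASNS at -1.32 and PSAT1, an enzyme of serine synthesis, at -1.29. Heat shock genes fell for 8 of 13 (9 adjusted over the list alone, adjusted p = 5.70e-06), with DNAJB1 at -1.08. MYC targets fell for 20 of 27 (22 adjusted over the list alone, median -0.38, adjusted p = 8.72e-11), AMD1 at -1.32, with adjusted p = 0.0613 with an estimated correlation. ER chaperones fell for 7 of 17 and rose for 1, also adjusted over the list alone (adjusted p = 0.000325, adjusted p = 0.0917 with an estimated correlation), HSPA5 at -1.23. FOXO targets rose for 9 of 23 and fell for 2 (12 and 3 adjusted over the list alone, median 0.26, adjusted p = 0.000904), with TXNIP at 0.96 (0.25 in DHL4, not called there, and 1.67 in DHL6). TXNIP had fallen at 2 h, at -1.31 (-1.58 in DHL4, -1.04 in DHL6). Interferon genes rose for 8 of 28, also adjusted over the list alone (adjusted p = 0.00174), SP110 by 1.47. B-cell receptor components rose for 9 of 23 and fell for 3, also adjusted over the list alone (adjusted p = 0.00449, adjusted p = 0.0669 with an estimated correlation). Ribosomal protein genes rose for 8 of 29 (9 adjusted over the list alone, median 0.08, adjusted p = 0.00267, adjusted p = 0.0649 with an estimated correlation), a call also lost after centring (median 0.01) and quantile normalization (0.08). Germinal centre genes rose for 6 of 15 and fell for 3 (7 and 3 adjusted over the list alone, median 0.21, adjusted p = 0.0422, adjusted p = 0.119 with an estimated correlation), with MME at 1.39, and lost the call without replicate 2 of DHL4 in DMSO (median 0.20), replicate 1 of DHL4 at 48 h (0.20) or replicate 2 of DHL6 at 48 h (0.19). Limma called 2584 genes, 967 higher and 1617 lower, 96 and 183 of them by at least 2-fold. The split depended on scaling, with 1304 higher and 1236 lower after quantile normalization and 625 and 1955 after centring. With the arrays' ACTB 3'-minus-5' difference, a measure of RNA quality, as a covariate, 851 genes were called.

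Camera calls that held with an estimated correlation were cholesterol, fatty acid and heat shock genes at all 4 times, MYC targets at 2, 6 and 24 h, FOXO targets at 6, 24 and 48 h, DNA replication genes at 24 and 48 h, interferon genes at 24 and 48 h, NF-kB targets at 2 and 6 h, ER chaperones at 2 and 6 h, immediate early and MHC class II genes at 6 h, ribosomal proteins and B-cell receptor components at 24 h, and mitosis and ATF4 genes at 48 h.

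**Figure D1:**
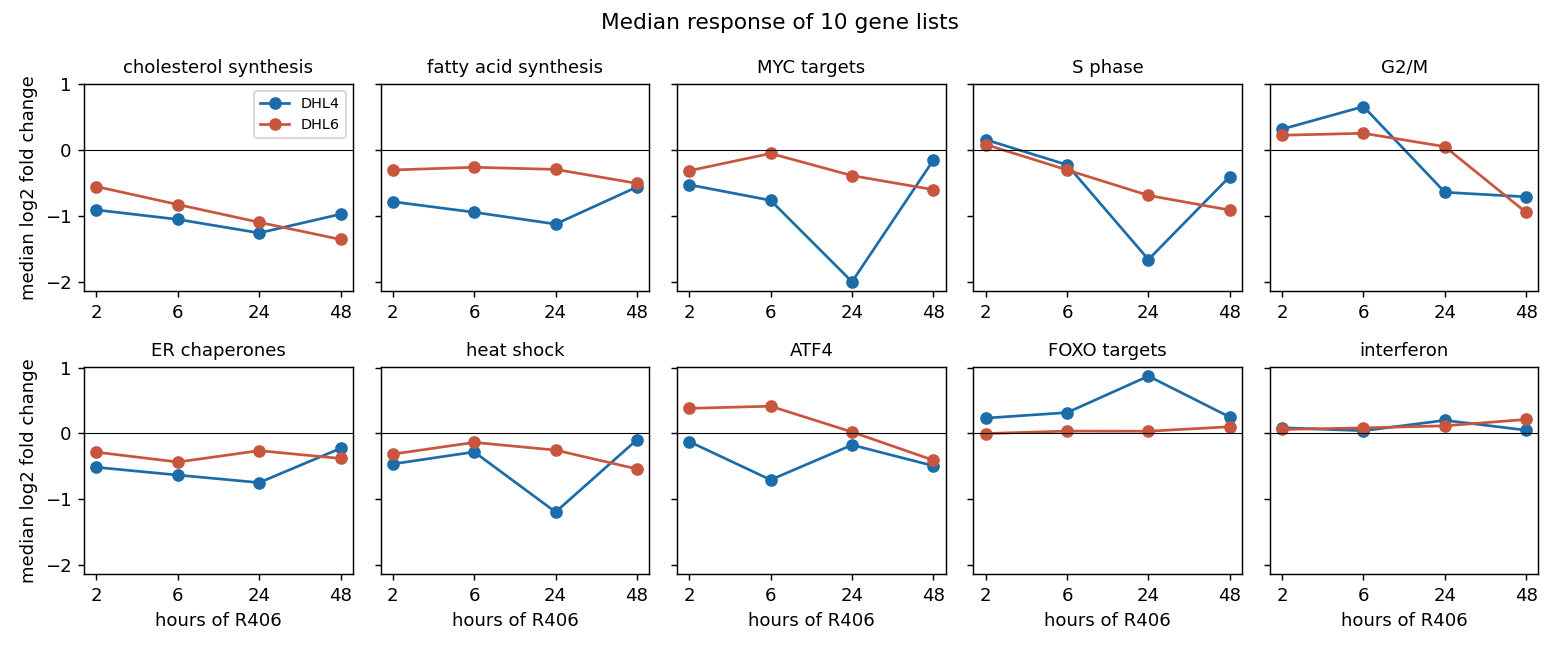
Median log2 fold change of R406 against DMSO (vertical axis) over the measured members of 10 gene lists, by time (evenly spaced, not to scale) and line. The cholesterol list lies below 0 in both lines at all 4 times, with medians of -0.97 in DHL4 and -1.36 in DHL6 at 48 h.

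Line by line, the count of changed genes was highest at 24 h in DHL4, while in DHL6 the order of 24 h and 48 h depended on the processing. As deposited, DHL6 had 1748 at 24 h and 2831 at 48 h, but 871 and 208 with the ACTB covariate, 2454 and 1311 without 4 arrays of narrow range, 2755 and 2621 with array weights, and 2422 and 1727 with only the compared groups in the fit. With the covariate the median SE at 48 h rose from 0.161 to 0.338 over 3269 genes called at either time. Their median absolute log2 change stayed larger at 48 h, 0.47 against 0.40 at 24 h (0.62 against 0.47 as deposited). Without the 4 arrays of narrow range it was 0.45 at 48 h, on 1 DHL6 array, against 0.47 at 24 h. These genes were chosen by their calls as deposited, which were more numerous at 48 h. A wider SE can also raise a median absolute change. MYC, a growth-promoting transcription factor, fell in DHL4 by 1.31, 1.33 and 1.34 at 2, 6 and 24 h (SE 0.08) and stood at 0.19 at 48 h (adjusted p = 0.231), while in DHL6 it rose by 0.96, 1.11, 1.00 and 0.74 (SE 0.07). HRK in DHL4 rose from a log2 level of 3.60 in DMSO to 8.37 at 24 h and stood at 4.04 at 48 h. In DHL6 it rose from 4.62 to 7.70 and 8.11. In DHL4 at 24 h, 25 of 27 MYC targets fell (25 adjusted over the list alone, median -1.999, adjusted p = 1.83e-24), and at 48 h 3 fell (3 fell and 1 rose adjusted over the list alone, median -0.15, adjusted p = 0.0263, adjusted p = 0.537 with an estimated correlation). In DHL6, 14 fell at 24 h (16 adjusted over the list alone, median -0.39, adjusted p = 3.94e-11, adjusted p = 0.0630 with an estimated correlation) and 22 at 48 h (24 adjusted over the list alone, median -0.60, adjusted p = 2.01e-14). ATF4 targets rose in DHL6 at 6 h for 10 of 21 members and fell for 1 (12 and 1 adjusted over the list alone, median 0.41, adjusted p = 8.77e-09), and fell in DHL4 for 11 (11 adjusted over the list alone, median -0.71, adjusted p = 1.09e-09). BCL2L11, a death-promoting BCL2 family member, rose in DHL6 at 24 h by 0.65 ± 0.18 (adjusted p = 0.0136).

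Limma called 1153, 1555, 3593 and 892 genes in DHL4 at 2, 6, 24 and 48 h (325, 781, 1585 and 430 higher) and 644, 1005, 1748 and 2831 in DHL6 (260, 382, 754 and 1021 higher). The falling genes numbered 828, 774, 2008 and 462 in DHL4 and 384, 623, 994 and 1810 in DHL6. After quantile normalization 556 rose and 648 fell in DHL4 at 2 h and 598 and 506 at 48 h, 586 and 592 in DHL6 at 6 h, and 1308 and 1254 in DHL6 at 48 h, where centring gave 585 and 2219. For DHL4 at 6 h centring gave 728 and 771. The DHL6 arrays at 48 h, in which genes of DNA replication (24 of 28, 25 adjusted over the list alone, median -0.91, adjusted p = 1.09e-17) and MYC targets fell, also had the highest ACTB 3'-minus-5' difference, 2.32 ± 0.14 (SD, n = 3) against 1.47 ± 0.14 (SD, n = 3) in DMSO (two-sided exact permutation p = 0.1, the smallest 3 against 3 arrays allow, adjusted p = 0.32 over the times, lines and control genes). The DHL6 arrays at 2 and 24 h also lay above DMSO in that difference (1.80 and 1.86), as did those at 24 and 48 h in the GAPDH 3'-minus-5' difference (0.17 and 0.21 against -0.01), each with an exact permutation p = 0.1 and adjusted p = 0.32. For ACTB in DHL4 at 48 h it was 1.38 ± 0.14 (SD, n = 3) against 1.43 ± 0.03 (SD, n = 2). Of the 3 DHL6 arrays at 48 h, replicates 1 and 3 had upper quartiles of 4.80 and 4.96, under 5 as on 4 of the 29 arrays. With that ACTB difference as a covariate, the DHL6 counts were 335 at 2 h, 871 at 24 h and 208 at 48 h, and without the 4 arrays of narrow range the count at 48 h was 1311, with 1 DHL6 array left at 48 h. In DHL4 the counts were 568 at 2 h and 492 at 48 h without replicate 1 of its DMSO arrays, and 697 at 2 h, 954 at 6 h and 416 at 48 h without replicate 2.

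**Figure D2:**
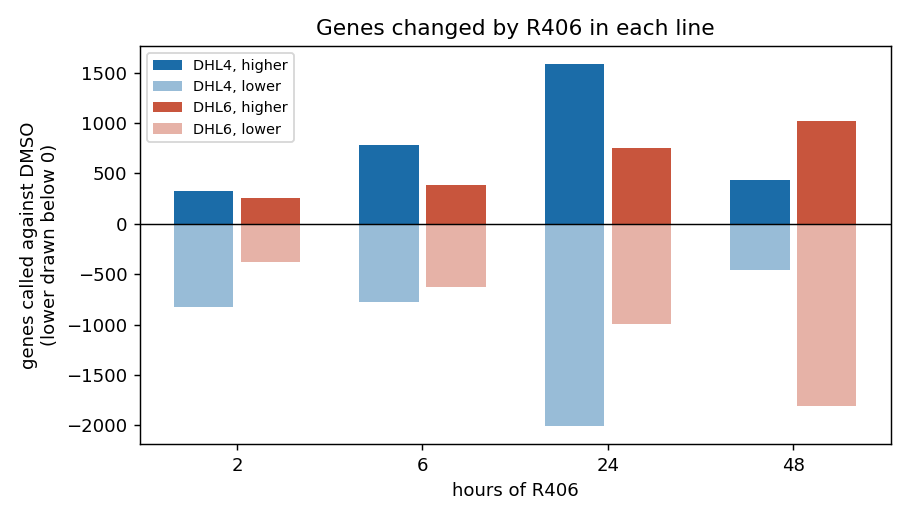
Number of genes called by limma (adjusted p below 0.05) as higher (bars above 0) or lower (bars below 0) in R406 than in DMSO, by line and hours of treatment. DHL4 had 1585 higher and 2008 lower at 24 h, and DHL6 had 1021 and 1810 at 48 h, or 1308 and 1254 after quantile normalization. With the ACTB covariate, DHL6 had fewer calls at 48 h (208) than at 24 h (871).

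The responses of the 2 lines were tested against each other by their difference, DHL6 minus DHL4. MYC differed at all 4 times (2.27, 2.44, 2.34 and 0.56, SE 0.11), and SYK at 6 h (0.90 ± 0.26) and 48 h (2.09 ± 0.26). HRK differed upward at 2 h (1.98 ± 0.34) and 48 h (3.05 ± 0.34) and downward at 24 h (-1.69 ± 0.34). HRK in DHL4 started near the floor (3.60), so its rises there are lower bounds. Its upward differences may therefore be overstated and its downward difference understated. TSC22D3, a glucocorticoid-induced regulator and FOXO target, differed most at 24 h (-5.92), with 4.50 in DHL4 and -1.42 in DHL6. By list, ATF4 targets responded higher in DHL6 at 6 h for 13 of 21 members (16 adjusted over the list alone, median 1.03, adjusted p = 6.45e-21) and at 2 h for 6 (11 adjusted over the list alone, median 0.59, adjusted p = 9.21e-11). At 24 h, MYC targets responded higher in DHL6 for 22 of 27 (22 adjusted over the list alone, median 1.45, adjusted p = 2.45e-23), heat shock genes for 9 of 13 (9 adjusted over the list alone, median 0.70, adjusted p = 8.83e-08) and glycolysis genes for 11 of 19 (11 adjusted over the list alone, median 0.65, adjusted p = 8.09e-07). FOXO targets responded lower for 15 of 23 and higher for 1 (16 and 2 adjusted over the list alone, median -0.84, adjusted p = 1.42e-08), and MHC class I genes lower for 5 of 10 (6 adjusted over the list alone, median -0.73, adjusted p = 0.000198). These calls held with an estimated correlation. Limma called 214 genes for the difference at 2 h (149 higher in DHL6, 65 lower), 857 at 6 h (375 and 482), 1989 at 24 h (1138 and 851) and 618 at 48 h (197 and 421). With the ACTB covariate 35 were called at 48 h, and without the 4 arrays of narrow range 352. After quantile normalization the split was 124 and 94 at 2 h and 327 and 341 at 48 h. Single arrays moved these counts. Without replicate 1 of DHL4 in DMSO 102 genes were called at 2 h, without its replicate 2 there were 133 at 2 h, 514 at 6 h and 236 at 48 h, and at 48 h there were 402 without replicate 1 of DHL6 in DMSO, 403 without replicate 1 of DHL4 at 48 h and 1239 without replicate 2 of DHL6 at 48 h.

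Changes also recurred across the lines, which share no arrays. At 24 h, 477 genes rose in both lines and 697 fell in both, where independent lists would share 98.2 and 164.1, and 88 changed in opposite directions. The fold changes of the lines correlated across genes at Pearson r = 0.55 (Spearman rho = 0.46) at 24 h, 0.50 (0.38) at 2 h, 0.33 (0.21) at 6 h and 0.44 (0.33) at 48 h. Shared calls numbered 104 up and 233 down at 2 h (6.95 and 26.1 for independent lists), 162 and 205 at 6 h (24.5 and 39.6) and 192 and 334 at 48 h (36.1 and 68.7). The numbers for independent lists treat all 12165 genes as equally likely to be called. Genes at the floor in both lines can hardly be called in either. The overlap can therefore exceed these numbers without a shared response. In the plot of values per array, HMGCS1, PTPN6 and BACH2 changed in the same direction in both lines at all 4 times, and MYC in opposite directions at 2, 6 and 24 h.

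**Figure D3:**
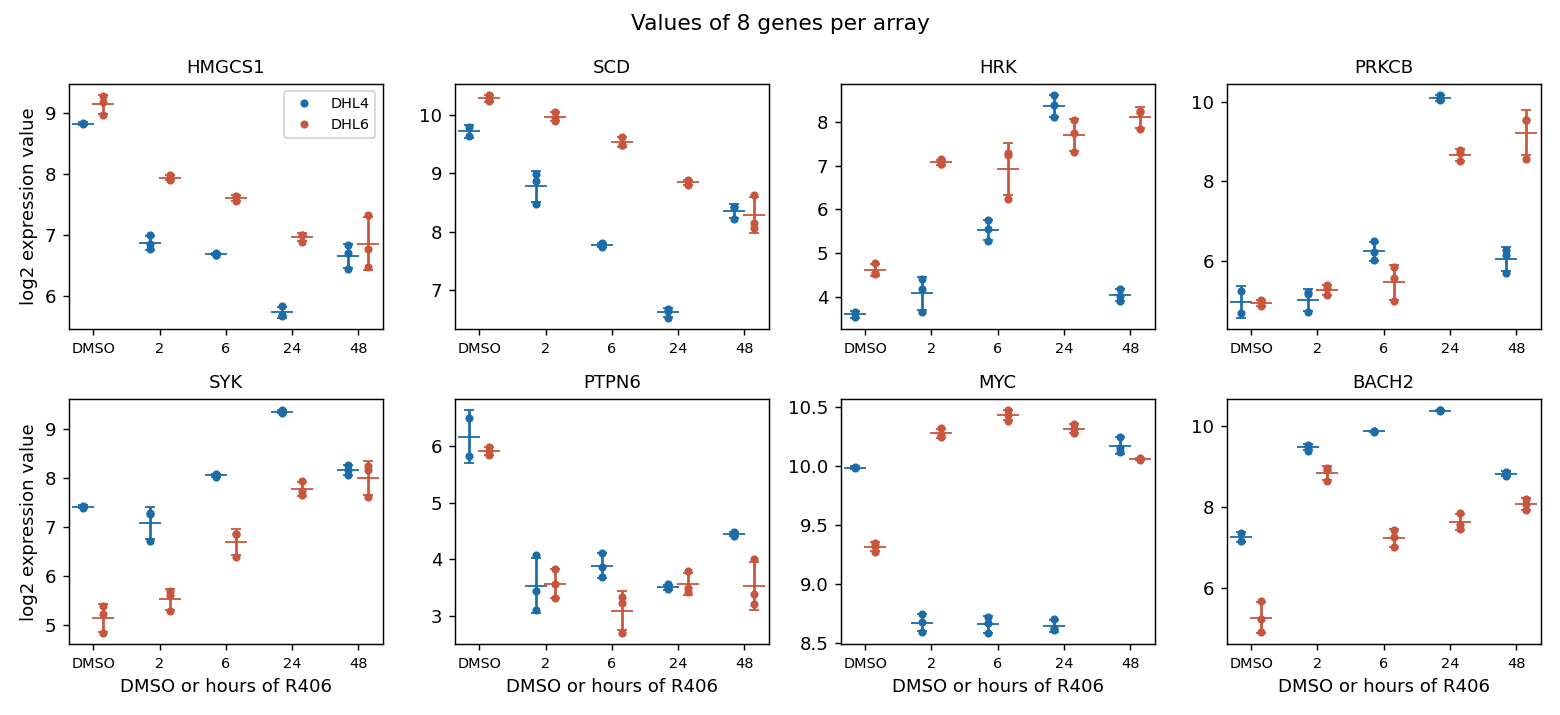
Log2 expression (vertical axis) of HMGCS1, SCD, HRK, PRKCB, SYK, PTPN6, MYC and BACH2 on every array, by line and treatment time (evenly spaced, not to scale), with points for arrays and bars for the group mean and SD. SYK rose from a mean of 5.16 in DMSO to 7.77 at 24 h in DHL6 and from 7.41 to 9.34 in DHL4.

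Late R406 arrays (24 and 48 h) were set against early ones (2 and 6 h) within each line, a comparison without DMSO. A fall here can be a return from an early rise and need not lie below DMSO. CDC25C in DHL4 had stood above DMSO by 1.81 at 2 h and 2.26 at 6 h, and CHAC1 in DHL6 by 1.77 and 1.83. The late arrays also pool 24 and 48 h, between which 3055 genes differed in DHL4 and 817 in DHL6. Cell cycle genes were lower late than early in both lines. In DHL4 all 29 mitosis genes fell (29 adjusted over the list alone, median -1.33, adjusted p = 1.34e-42), among the largest PLK1 (-2.05), CDC25C (-1.91) and MKI67 (-1.89), along with RNASEH2A (-1.87), and 26 of 28 DNA replication genes fell (27 adjusted over the list alone, median -0.97, adjusted p = 5.19e-28). In DHL6, 26 mitosis genes (26 adjusted over the list alone, median -0.60, adjusted p = 9.59e-22) and 25 DNA replication genes fell (26 adjusted over the list alone, median -0.70, adjusted p = 9.11e-25). B-cell receptor components were higher late in DHL4, 13 against 1 lower (15 and 1 adjusted over the list alone, median 0.51, adjusted p = 1.36e-08), and in DHL6, 11 against 1 (11 and 1 adjusted over the list alone, median 0.21, adjusted p = 1.35e-06). DHL4 also showed higher MHC class I genes, 8 of 10 (9 adjusted over the list alone, median 0.66, adjusted p = 2.08e-07). DHL6 showed lower ATF4 targets, 14 of 21 (15 adjusted over the list alone, median -0.52, adjusted p = 2.53e-15), and lower NF-kB targets, 8 against 1 higher (9 and 1 adjusted over the list alone, median -0.27, adjusted p = 3.18e-06). These calls held with an estimated correlation. DEPP1 (2.63), PECAM1 (2.45), PRKCB (2.44), CD72 (2.43) and NOTCH2NLA (2.34) rose most in DHL4. In DHL6 PRKCB (3.58), H2BC8 (3.29), SMAD1 (2.98), PHYH (2.32) and MAD1L1 (2.26) rose most, and CD83 (-2.15), CTH (-1.93), CHAC1 (-1.86), TNFAIP3 (-1.65) and PSAT1 (-1.60) fell most. Limma called 2777 genes in DHL4 (1433 higher, 1344 lower) and 1987 in DHL6 (769 higher, 1218 lower). For DHL4 the split was 1491 and 1463 after quantile normalization and 1154 and 1562 after centring. For DHL6 it was 1097 and 1081 after quantile normalization and 569 and 1431 after centring, and the count was 546 with the ACTB covariate.

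In DMSO the lines differed before any R406, among others in IGHM and SYK. IGHM, the heavy chain of surface IgM, stood at a log2 level of 10.3 in DHL6 and 2.66 in DHL4 (difference at least 7.66 ± 0.18, DHL6 minus DHL4, 3 against 2 arrays), and SYK was lower in DHL6 (-2.25 ± 0.19). UCHL1 (6.07), S100A10 (5.93), VIM, vimentin (5.89), and MDFIC (4.71) were the next highest in DHL6. TUBB6 (-5.98), HTR3A (-5.97), GSTO1 (-5.77), DCN (-5.65) and RASGRP1 (-5.39) were the lowest. In each of these 10 genes the lower line lay at or near the RMA floor, from 2.66 for IGHM and 2.78 for DCN to 3.81 for GSTO1, where array medians in DMSO ran from 3.11 to 3.15. The differences are lower bounds, so their order is not a measured order. EGR1 (2.76 ± 0.33, DHL4 near the floor at 3.23) and HRK (1.02 ± 0.25, DHL4 near it at 3.60) were higher in DHL6 and MYC (-0.67 ± 0.08), TXNIP (-1.59 ± 0.18), DUSP6 (-0.96 ± 0.16), BCL6 (-0.52 ± 0.14) and INSIG1 (-0.64 ± 0.14) lower. Limma called 2500 genes, 1217 higher and 1283 lower in DHL6, or 1221 and 1198 after centring.

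Several lists passed the camera test at no time in the mean of both lines, although single members changed. Counts adjusted over the list alone follow each count in brackets. Among death-promoting BCL2 family genes, 4 of 12 rose and 2 fell at 24 h (5 and 2), with HRK, PMAIP1 (1.13) and BNIP3L (0.95, called in DHL4 only) higher and BID (-0.99, called in DHL4 only) lower, and the lowest adjusted p over the times was 0.135. Of 6 survival-promoting members, 1 fell at 24 h (1), BCL2A1 (-0.71 in the mean, lowest adjusted p = 0.771), with opposite signs in DHL4 (0.57, not called) and DHL6 (-1.99). BCL2L11 stood at 0.32 ± 0.13 in the mean at 24 h (adjusted p = 0.0743). Of 8 sterol efflux genes, 2 rose at 24 h (2), ABCA1 (1.42) and MYLIP (1.01, lowest adjusted p = 0.0804), both in DHL4 only (2.83 and 2.02, against 0.01 and 0.01 in DHL6). Of 13 ERK feedback genes, 1 rose and 1 fell at 24 h (1 and 1), with DUSP5 at -0.81 (lowest adjusted p = 0.799). DUSP6, a phosphatase of ERK, stood at -0.02 ± 0.11. Of 12 receptor-induced chemokines and activation markers, 3 rose and 5 fell at 24 h (4 and 6), with CD69 at 2.13 (4.22 in DHL4, from the floor at 2.62, and 0.03 in DHL6, lowest adjusted p = 0.501), and of 9 NFAT and calcium-induced genes 3 fell at 48 h (3), RGS2 at -1.22 (lowest adjusted p of the list = 0.0620). Among 13 G1 cyclins and CDK inhibitors, 3 rose and 2 fell at 24 h (3 and 2), CDKN1B by 1.88 (3.23 in DHL4, 0.53 and not called in DHL6) and CDK4 at -1.78 (lowest adjusted p = 0.401), and CCND2 stood at 0.03 ± 0.12. Of 16 p53 targets, 7 rose and 3 fell at 24 h (8 and 3), XPC by 1.16 and BAX at -0.85 (-0.23 and not called in DHL4, -1.46 in DHL6, list adjusted p = 0.0646). The other BAX probe set, at -0.29, was not called. KLF2, a FOXO target, stood at 0.14 ± 0.12 at 24 h. BCL6, the germinal centre repressor, fell at 2 h (-0.62 ± 0.09) and 6 h (-0.51) and rose at 48 h (0.44 ± 0.09) in the mean of both lines. At 2 and 48 h it was called in DHL4 only (-1.08 and 0.83). Its other probe set fell in the mean at 2 and 6 h (-0.76 and -0.45) but stood at -0.03 at 48 h and was not called. The rise at 48 h therefore rests on 1 probe set. INSIG1, which restrains sterol synthesis, fell at all 4 times, by 0.73, 1.24, 1.01 and 1.19 (SE 0.09).

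Of 11 NRF2 targets, 3 fell and 1 rose at 24 h (3 and 1, adjusted over the list alone), TXNRD1 at -1.02 (lowest adjusted p of the list = 0.400). Of 10 aryl hydrocarbon receptor targets, 2 rose and 1 fell at 24 h (2 and 1, lowest adjusted p = 0.131), and CYP1A1, a xenobiotic-metabolising enzyme, stood at 2.29 ± 0.29 in DHL4 and -0.06 ± 0.26 in DHL6. Of 19 autophagy and lysosome genes, 4 rose and 4 fell at 24 h (6 and 4, lowest adjusted p = 0.261), MAP1LC3B by 1.08 and TFEB, a regulator of lysosome genes, at -1.03. Where lists were not called, median, mean and test could differ in sign, as for the survival-promoting, ERK feedback, chemokine, NFAT, germinal centre, plasma cell, MHC class II, T-cell, fibroblast and pan-B-cell lists at 1 or more times. Medians of oxidative phosphorylation at 48 h (-0.06, 4 rose and 2 fell, 4 and 2 adjusted over the list alone, adjusted p = 0.920) turned to 0.05 after quantile normalization.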

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

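Of the tests in this part, those of untreated cells, normalization, arrays of narrow range and 3' bias were chosen only after the result was seen, while the sample splits, the difference between the lines in the change from 24 to 48 h, and culture time were set before.

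The responses of the lines differed in 214, 857, 1989 and 618 genes at 2, 6, 24 and 48 h, each by limma's test of the difference, DHL6 minus DHL4. At 2 h the log2 differences were 3.84 for USP2, 2.94 for RGS16, 2.64 for BCAR3, -3.25 for LRRN3, -2.25 for BHLHE40 and -2.12 for TMEM156, and among genes fixed in advance 0.92 for BCL6, 1.98 for HRK, 2.27 for MYC and 0.87 for SQLE. USP2 lay at the floor in DHL6 (2.70 in DMSO), so its difference is the fall in DHL4 from 6.72 to 2.98. At 6 h they were 3.73 for USP2, 3.28 for PSAT1, 3.20 for LIMA1, -3.45 for RAPGEF2, -3.21 for TNFRSF17 and -3.21 for SATB1, and -1.57 for EGR1, 2.44 for MYC, 0.89 for SQLE and 0.90 for SYK. At 24 h they were 5.73 for HTR3A, 4.25 for LIMA1, 4.19 for DEPTOR, -5.92 for TSC22D3, -5.43 for FCMR and -5.41 for DEPP1, and -2.35 for CYP1A1, -2.51 for EGR1, 0.91 for HMGCS1, -1.69 for HRK, 2.34 for MYC, 0.74 for SQLE and -0.71 for TXNIP. HTR3A lay at the floor in DHL6 and EGR1 near it in DHL4. At 48 h they were 4.45 for APOD, 4.22 for PHYH, 3.87 for SMAD1, -3.08 for TUBB2B, -3.03 for LTB and -2.92 for HLA-DOB, and -0.78 for BCL6, 0.99 for DUSP6, 3.05 for HRK, 0.56 for MYC, 2.09 for SYK and 1.42 for TXNIP. APOD (2.78), PHYH (3.34), HRK (3.60) and CYP1A1 (3.07) lay at or near the floor in DHL4 in DMSO, so their rises there are lower bounds. Their positive differences, as at 48 h, may therefore be overstated. The negative differences of HRK and CYP1A1 at 24 h may be understated.

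Probe sets with several symbols or no listed gene lay outside the comparisons. At 24 h limma called 582 of 2491 such probe sets in the mean of both lines, 302 higher and 280 lower. That is 23.4%, against 30.9% of the named genes.

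Other assignments of the arrays to groups were fitted 100 times per result, the real one included. For the mean of both lines, the DMSO and R406 labels of a time were permuted within each line, and for late against early the times were permuted among the R406 arrays. In the mean of both lines, 1 of 100 gave as many called genes at 2 h (1591, highest other 991), 6 h (1783, 970), 24 h (3757, 2729) and 48 h (2584, 2192). A random assignment of single arrays can thus be excluded for these counts. Arrays of a group may share 1 culture, so chance differences between cultures cannot. The number of called gene lists was reached by 33, 14, 30 and 9 of 100 (7, 13, 14 and 13 lists, highest other 14, 15, 21 and 14), so chance cannot be excluded for how many lists were called. The correlation of the lines' fold changes was reached by 1, 1, 1 and 2 of 100 (0.50, 0.33, 0.55 and 0.44, highest other 0.44, 0.31, 0.53 and 0.47). This too excludes only a random assignment of single arrays. Late against early was reached by 1 of 100 in DHL4 (2777, highest other 1983) and 1 in DHL6 (1987, 1331). Permuted groups there hold arrays of different times, which widens the spread within groups. The result therefore excludes a random assignment of single arrays, and not a chance difference between whole groups. For the mean of both lines, a permuted assignment that leaves the arrays of 1 line as labelled, or nearly so, still holds the response of that line, so high values in other splits can come from the response itself. For DHL6 alone, 3 against 3 arrays make 10 splits, too few for a share under 0.05, with 644, 1005, 1748 and 2831 genes in the real split, reached by 1 split each, and 0, 2, 0 and 1 in the highest other.

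The DHL4 response was smaller at 48 h than at 24 h (892 against 3593 genes), and as deposited that of DHL6 was not (2831 against 1748). Chance spread between these arrays is argued against by 2653 genes called for the difference between the lines in their change from 24 to 48 h. Normalization is argued against by a ratio of the DHL4 counts of 0.303 after quantile normalization. For 3' bias as the cause of the DHL4 drop, the ratio was 0.265 with the ACTB covariate (924 against 3483). In DHL4 the ACTB 3'-minus-5' difference lay near DMSO (1.43) at 24 h (1.55) and 48 h (1.38). No large ACTB shift was thus seen in DHL4. The covariate could therefore hardly change these counts, and the ratio cannot decide the question. If the DHL4 arrays at 48 h held untreated cells, the cholesterol list should lie near its DMSO level, and its median log2 fold change was -0.97. This cannot decide the question, because untreated cells grown for 48 h may differ from DMSO arrays without a stated time. The DHL6 part is not established. Without the 4 narrow-range arrays the order of the counts turned (ratio 0.534), but on 1 array at 48 h, assumed to vary like the other groups. The median absolute log2 change of the 3269 genes called at either time as deposited turned there as well (0.45 at 48 h against 0.47 at 24 h). With the ACTB covariate the order of the counts turned too (208 against 871, ratio 0.239), while the median SE at 48 h rose from 0.161 to 0.338. The median absolute change of these genes then stayed larger at 48 h (0.47 against 0.40). Their choice by calls as deposited favours 48 h, and a wider SE can raise such a median. Neither explanation can therefore be told apart from the response there. Culture time, with 3055 genes differing between 48 and 24 h in DHL4 and 817 in DHL6, cannot be told apart from treatment time, because the labels give the DMSO arrays no time. A recovery of DHL4 from R406 may also underlie its drop and stays open as a hypothesis.

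In DHL6 at 48 h more genes fell than rose (1810 against 1021). After quantile normalization 51.1% of calls rose, which decides nothing about arrays of narrow range, because that share lay between 46.2% and 56.9% in all 19 contrasts. The ACTB 3'-minus-5' covariate brought the median of the 1810 falling genes from -0.76 to -0.49, a ratio of 0.643 between the bounds set for it, while their median SE rose from 0.172 to 0.357 and the covariate itself passed for 0 genes by limma, so most of the lost calls may reflect the wider SE. Neither explanation can be told apart from the response to R406 here. No biological explanation was tested for the split.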

How the results depend on the processing

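All alternatives but the last pair here were fixed before the data were examined; leaving out 4 narrow-range arrays and the ACTB covariate were chosen after seeing the data. Of 735 named-gene results, 622 were called, and none was reversed in 7429 values with an array left out (303 lost the call) or in 8065 values under other alternatives (209 lost it and 50 gained it, 0 reversed). Several of these other alternatives keep a named gene's fold change, so they could change its call but not its sign. They are the trend and robust settings, only the compared groups, all probe sets and leaving out the dimmest genes. Leaving out the narrow-range arrays does so for groups without such arrays. Over 267 called gene and time results in the mean of both lines whose gene had other probe sets, 287 of these 482 were called the same way, 195 were not called and 0 were called the opposite way. In 69 of the 267 no other probe set was called, among them KANK2 at 2 and 6 h (0.08 and 0.28, against 2.01 and 2.73), FASN at 4 times (0.05 to 0.27, against -1.19 at 2 h and -1.97 at 24 h), HRK at 2, 6 and 48 h (-0.02 to 0.42), PIK3CD at 24 h (0.17 against 1.64) and EGR1 at 24 h (0.28 against -1.33), so these rest on 1 probe set. The number of arrays and dim signals near the RMA floor limit what can be seen. The spread also differed between groups, with a median gene SD of 0.207 in DHL6 at 48 h, 0.139 in DHL6 at 24 h and 0.107 in DHL6 in DMSO. The model shares 1 estimate of spread over all groups, so its SE for DHL6 at 48 h may be too small and its count there too high. For the values that follow the cause was not tested, except that fewer groups in a fit or fewer arrays leave fewer degrees of freedom.

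After quantile normalization 12 gene lists were called at 2 h, and the oxidative phosphorylation median at 48 h, called neither way, changed from -0.06 to 0.0477. Array weights gave 2337 and 1611 genes in DHL4 at 6 and 48 h, 1155, 1648 and 2755 in DHL6 at 2, 6 and 24 h, and 350, 1450 and 1126 for the difference between lines at 2, 6 and 48 h. With only the compared groups in the fit there were 510 in DHL4 at 2 h, 1727 in DHL6 at 48 h, 404 for the difference at 48 h and 1267 for late against early in DHL6. Camera with an estimated correlation called 9 lists at 24 h and 8 at 48 h, and fry, which does not compare a list with other genes, 20, 26, 24 and 25 at the 4 times. Without the 4 narrow-range arrays there were 1528 genes in DHL4 at 48 h, 1070 and 1311 in DHL6 at 2 and 48 h, and 335 and 352 for the difference at 2 and 48 h. The ACTB covariate gave 851 genes in the mean at 48 h, 335, 871 and 208 in DHL6 at 2, 24 and 48 h, 35 for the difference at 48 h and 546 for late against early in DHL6, with correlations of the lines of 0.377 at 2 h and 0.504 at 24 h.

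With each array left out in turn, counts ran from 1047 to 1585 in the mean at 2 h, from 568 to 1232, 954 to 1308 and 416 to 759 in DHL4 at 2, 6 and 48 h, and from 102 to 252, 514 to 864 and 236 to 1239 for the difference at 2, 6 and 48 h. Lists called at 2 h ran from 7 to 11, and the correlation at 24 h from 0.533 to 0.557. Replicate 1 of DHL4 in DMSO gave the lows of 1047, 568 and 102, the 11 lists and 492 in DHL4 at 48 h. Replicate 2 gave the lows of 954, 416, 514 and 236, and 697 in DHL4 at 2 h. At 48 h the difference was 402 without replicate 1 of DHL6 in DMSO, 403 without replicate 1 of DHL4 at 48 h and 1239 without replicate 2 of DHL6 at 48 h. Where 1 DHL4 DMSO array was left, or 1 DHL6 array at 48 h without the narrow-range arrays, it was assumed to vary like the other groups.

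Replicate numbers did not pair the samples. Arrays of the same number within a line correlated in their deviations from group means at 0.011 on average in DHL4 and -0.033 in DHL6, and 6 of 14 and 3 of 15 arrays were closest to their own number. With the replicate number as a block, 3637 genes were called in the mean at 24 h, 2334 at 48 h, and 1752 between the lines in DMSO, and no count moved by more than 1.5 times.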

Other observations

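The MYC test reported at the end of this part was chosen only after the result was seen.

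Markers of other cell types were on the arrays as well. Of 13 T-cell markers only LCK, a tyrosine kinase also expressed in some B-cell tumours, changed in the mean of both lines (1 lower at each time, 1 adjusted over the list alone). It fell by 1.31, 1.32, 1.59 and 1.12 at 2, 6, 24 and 48 h (SE 0.16), from DMSO levels of 7.63 in DHL4 and 7.50 in DHL6, and the lowest adjusted p of the list was 0.716. Of 12 monocyte and macrophage markers 0 were called at any time by limma, also adjusted over the list alone (lowest adjusted p of the list = 0.291). Of 12 fibroblast and endothelial markers, 1 rose and 2 fell at 24 h, also adjusted over the list alone (lowest adjusted p = 0.160). In DHL4, DCN went from a log2 level of 8.43 in DMSO to 4.42 at 24 h and 8.68 at 48 h, THY1 from 6.05 to 3.45 and 6.41, and PECAM1, an adhesion receptor, from 3.08 to 7.64 and 4.79. Their responses differed between the lines at 24 h by 4.12, 2.57 and -4.32 (DHL6 minus DHL4), with DCN, THY1 and PECAM1 near the floor in DHL6 (2.78, 2.80 and 2.66 in DMSO).

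Single members of the pan-B-cell, plasma cell, histone and MHC class I lists changed at 24 h, while none of these lists was called then. Of 9 pan-B-cell genes, 3 rose and 3 fell at 24 h, also adjusted over the list alone (lowest adjusted p of the list = 0.182), with TCL1A at 2.52 ± 0.10 and CD79B, a receptor signalling subunit, at 1.57 ± 0.07, against VPREB3 at -1.97 ± 0.21 and MS4A1, the CD20 antigen, at -1.70 ± 0.07. Of 13 plasma cell genes, 2 rose and 4 fell at 24 h, also adjusted over the list alone (lowest adjusted p = 0.291), with CD27 at 2.09 and TNFRSF17, the BCMA receptor, at -2.38. Of 12 histone genes, 5 rose and 1 fell at 24 h (6 and 2 adjusted over the list alone, lowest adjusted p over the times 0.0584), H2BC5 by 2.20, H2AC6 by 1.99 and H2BC12 by 1.82. The histone list passed at 2 h after centring (median 0.08) and after quantile normalization (0.17), among other alternatives. MHC class I genes rose for 4 of 10 at 24 h and 3 at 48 h, also adjusted over the list alone (adjusted p = 0.0672 and 0.0624), with HLA-B at 0.66 and 0.70.

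A hypothesis was that the MYC transcript alone sets the MYC target list, since MYC fell in DHL4 and rose in DHL6. It needs a median above 0 for these targets in DHL6 at 24 h, where MYC stood at 1.00. The median was -0.39, with 14 of 27 members lower (16 adjusted over the list alone, adjusted p = 0.0630 with an estimated correlation), which argues against MYC transcript level as the whole explanation. Other inputs to these genes may be involved and were not tested.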
